A study of Homo sapiens with 9 samples.

How the data were processed

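The series holds 9 samples of NK92 cells at 12 passages, per the labels. Of these, 8 have a peak list: H3K27ac and RUNX3, each in untreated cells and in cells given 1000 nM SAHA for 24 hours, with 2 biological replicates per group. Groups and replicate numbers were taken from the sample titles. The input library was not analysed here. Per the labels' protocols, fixed chromatin was sonicated and immunoprecipitated, libraries were made by tagmentation (insertion of adapters by a transposase) and sequenced in pairs of reads, and several sequencing platforms are named without saying which library ran on which.

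The authors deposited 1 list of peaks per library, and the peak names show separate calls per library. Per the submitters' processing notes, BWA 0.7.12, Picard 2.27.4, MACS2 2.2.7.1 and deepTools 3.5.1 were used on hg19. The role and settings of each, and the control used in calling, are not given in the sources used here. The H3K27ac lists have the 9 columns of MACS2's broad layout and the RUNX3 lists the 10 columns of its narrow layout, and the RUNX3 peak names carry q0.1. Each deposited list gives a start and end, a score, a fold enrichment (a linear ratio over the background of that library's own call), a −log10 p-value and a −log10 q-value per peak, all the authors' values. The score is the whole part of 10 times −log10 q in 99.96% to 100.0% of the peaks of each list. The smallest −log10 q was 1.00 to 1.01 in every list. Numbers in the peak names run in genome order with gaps. Up to the last number, 1.93% to 2.00% of H3K27ac and 4.42% to 6.70% of RUNX3 numbers are missing, so called peaks had been left out of the deposited lists by a step that is not given in the sources used here. All listed peaks lay on chromosomes 1 to 22, X and Y. The fold enrichment, p and q of a peak belong to its own list and were used to rank, filter or match peaks and to describe each list, and read numbers were not used here, so depth is unknown and no interval for counting error is given.

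Positions are given 1-based. Per library, the number of peaks, the covered length and the median width were compared between treatments by two-sided exact permutation of 2 against 2 libraries, whose smallest p is 0.333. The similarity of 2 lists was the shared over the joint covered length in bp. For each antibody, peaks of the 4 libraries that overlapped by 1 bp or more were merged into regions. A region was called gained with a peak in both SAHA and neither untreated library, lost with the converse, and shared with a peak in all 4. The same count for the other 2 splits of the 4 libraries was set beside it. Regions were ranked by the percentile of the authors' fold enrichment within each list, using the region's strongest peak per library and taking the lower of the 2 libraries. Peak numbers skipped between the listed neighbours of a region were counted in the lists that lacked it, a check added after the data were examined.

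Covered length was also compared in bins of 50 kb with limma (moderated test with a trend on the mean) on log2(covered bp + 500) for H3K27ac and log2(covered bp + 200) for RUNX3, in bins with at least 500 or 200 bp in 2 or more libraries, with Benjamini-Hochberg adjustment at 0.05. Log2 changes are on that scale and understate changes from low values. Overlap of RUNX3 peaks with H3K27ac used both lists of the same treatment, 1 bp or more, and 100 circular shifts of the RUNX3 peaks along each chromosome as background. Changes of the 2 antibodies were compared by two-sided Fisher's exact tests on regions, with 95% intervals of the odds ratio.

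Tests, groupings and the other settings to try were fixed before the data were examined, except the lengthening of shared regions and its grouping by length, the number of long peaks, the median fold enrichment and the settings and checks said to be added. The plan set gene loci, 20 fixed gene lists, promoter shares and RUNX motifs where an annotation or genome of hg19 was at hand, and 50-kb bins otherwise. The gene table used here is on another assembly (GRCh38), so no gene names were given to peaks, and the gene, gene list, promoter and motif parts were not run. The rule for named items was a fixed set of genes, members of the lists, the 8 gained and 8 lost regions of highest rank, named by the nearest gene, and the 5 loci of largest change per direction past the threshold. It was applied to regions and bins by position and could not be applied to genes. The other settings were peaks of −log10 q 5 or more, the same number of top peaks per library, an overlap of 50% of each peak, joining peaks within 1 kb, other pseudocounts and minimum lengths, scaling by total covered length, the replicate block and leaving out each library.

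The limma step was tested on simulated bins. In the H3K27ac comparison (15322 bins) it recovered 84.0% of changes of 0.5, 100.0% of changes of 1 and of 2 and 88.0% of changes of −1 on the log2 scale, with 3.63% false calls. In the RUNX3 comparison (1675 bins) it recovered 0% at 0.5, 20% at 1, 80% at 2 and 2.00% at −1, with 1.92% false calls. The simulated noise depended only on a bin's mean, so these rates leave out differences in spread between bins of equal mean. The region step was tested on 29083 simulated H3K27ac regions with peaks missing at random, and found 88.3% of gained and 88.0% of lost regions where 90.3% could be found, with 19.1% of calls false. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.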

Results

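The binding of the transcription factor RUNX3 and the acetylation of lysine 27 of histone H3 (H3K27ac, a mark of active promoters and enhancers) were mapped in NK92 cells by chromatin immunoprecipitation and sequencing. NK92 is a human natural killer cell line that grows with interleukin-2. Cells were left untreated or were given 1000 nM SAHA (vorinostat, an inhibitor of histone deacetylases) for 24 hours. Each antibody was used on 2 untreated and 2 SAHA-treated biological replicates, which makes 8 libraries in 4 groups. A single input library of untreated cells was not analysed here. The data are 1 list of called peaks per library, with positions on hg19. The lists give no read numbers, so the sequencing depth of each library is unknown and a missing peak means only that none was listed.

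The first comparison asked how SAHA changed the extent of H3K27ac. Both SAHA libraries had more acetylated regions and more acetylated sequence than either untreated library. The number of H3K27ac peaks was 28306 ± 254 (SD, n = 2) in untreated cells and 32906 ± 73.5 (SD, n = 2) after SAHA, a rise of 16.3%. The length covered by peaks was 69.6 ± 0.972 Mb (SD, n = 2) in untreated cells and 87.9 ± 1.2 Mb (SD, n = 2) after SAHA, a rise of 26.3%. Peaks of 10 kb or longer numbered 794 ± 19.8 (SD, n = 2) in untreated and 1205 ± 31.1 (SD, n = 2) in SAHA-treated cells, 1.52 times as many, a count that includes peaks that lengthened past 10 kb. The median peak was 1654 bp long in both untreated libraries and 1659 ± 24.7 bp (SD, n = 2) after SAHA, a difference smaller than the spread between replicates. The median of the authors' fold enrichment per peak went the other way, from 4.55 ± 0.127 in untreated to 4.13 ± 0.0223 in SAHA lists (SD, n = 2; exact permutation p = 0.333), though each fold is relative to its own library's background. Untreated replicates shared 0.850 of their joint peak length and SAHA replicates 0.849, whereas pairs of different treatment shared 0.721 to 0.732. The differences in peak number, covered length and peaks of 10 kb or longer were larger than the spread between replicates. The two-sided exact permutation p of each was 0.333, the smallest that 2 libraries against 2 can give. Among peaks with a −log10 q of 5 or more the rise in peak number was 6.78%, against 24.9% for covered length.

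**Figure D1:**
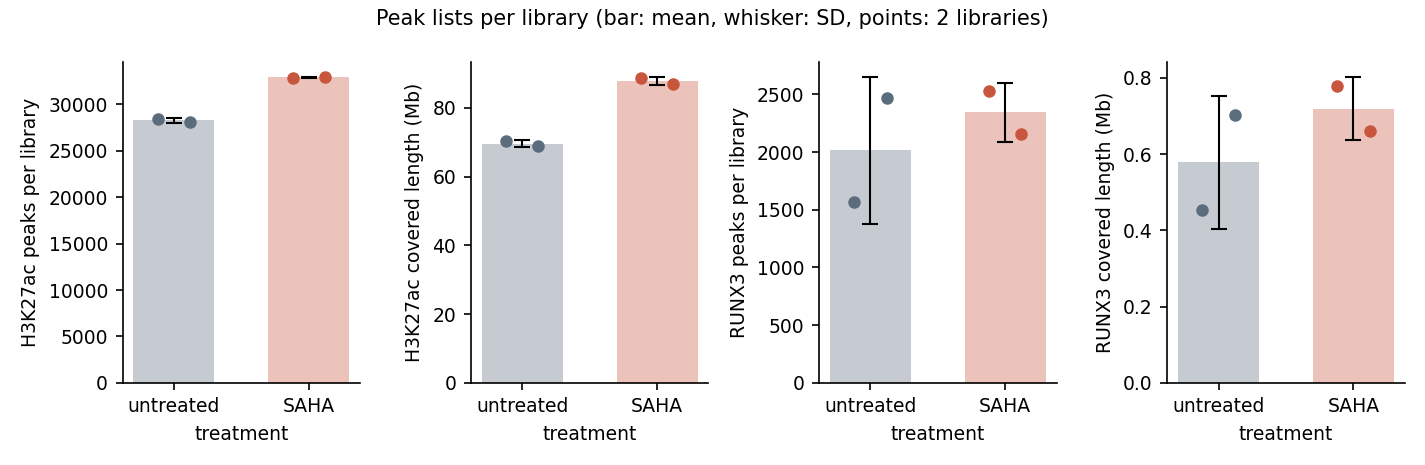
Peaks per library and length covered by peaks (Mb) for H3K27ac and RUNX3, in untreated and SAHA-treated cells. Bars are means, whiskers are SDs and points are the 2 libraries of each group. For H3K27ac both SAHA libraries lie above both untreated libraries, and for RUNX3 the points of the treatments overlap.

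New H3K27ac regions outnumbered lost ones after SAHA. When the peaks of the 4 libraries were merged into 36699 regions, 22510 (61.3%) held a peak in every library. A further 4333 regions (11.8%) were gained, with a peak in both SAHA libraries and in neither untreated one, and 445 (1.21%) were lost, with the converse. The other 2 ways of splitting the 4 libraries gave between 129 and 216 such regions per pair, though each of these pairs mixes the treatments and so does not measure replicate noise alone. Gained regions were short and weak, with a median width of 824 bp, against 2695 bp for regions found in all 4 libraries. By the authors' fold enrichment, the median gained region lay at the 16.3rd percentile of its SAHA list, taking the lower of the 2 replicates, and 51 of the 4333 lay above the 50th percentile. The median region of all 4 libraries lay at the 64.2nd percentile on the same measure. A region's strongest peak set its percentile, which favours wider regions that can hold several peaks. With the same number of top peaks from each library, 2202 regions were gained and 906 lost, and with only the peaks of −log10 q 5 or more 1343 were gained and 308 lost. Asking for an overlap of 50% of each peak, which also separates lengthened peaks, counted peaks of replicate 1 and not merged regions. On that other unit 6034 peaks were gained and 3152 lost. With 1 library of a group left out, the remaining library counted alone. Gained regions then numbered 7034 without SAHA replicate 1 and 7147 without SAHA replicate 2. Lost regions numbered 1057 and 1350 without untreated replicates 1 and 2, and 740 and 710 without SAHA replicates 1 and 2.

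The gained regions ranked highest by fold enrichment included chromosome 8 position 74258042 to 74259995 (1954 bp), chromosome 6 position 20836906 to 20839160 (2255 bp), chromosome 12 position 96736371 to 96738254 (1884 bp) and chromosome 9 position 101336963 to 101339264 (2302 bp). The regions on chromosomes 12 and 9 held a RUNX3 peak in all 4 RUNX3 libraries, untreated ones included. The region on chromosome 8 held one in 1 untreated and 1 SAHA library. The other 4 of the 8 highest were narrow, with widths of 211 to 340 bp, and lay on chromosomes 16, 17 and 19. Among lost regions, chromosome 9 position 79188142 to 79194791 (6650 bp) ranked highest, with a fold enrichment of 11.1 and 11.5 in the 2 untreated lists. Both SAHA lists skip 1 peak number between the neighbouring listed peaks, so a peak called within that gap was left out of each list, and whether acetylation was lost there cannot be read from the lists. Both SAHA lists also skip 3 numbers beside the lost region at chromosome 1 position 149815235 to 149815410 (176 bp). No number was skipped beside the other 6 highest lost regions, among them chromosome 1 position 199559364 to 199560787 (1424 bp), chromosome 21 position 40330664 to 40332173 (1510 bp) and chromosome 12 position 11687655 to 11688941 (1287 bp). These 3 held no peak of −log10 q 5 or more in either untreated library. The same was true of those at chromosome 8 position 143110392 and chromosome 4 position 152579892. Only the last of the 6, at chromosome 9 position 136242586 and 176 bp wide, held one in both untreated libraries. The gained region on chromosome 12 held one in 1 of the 2 SAHA libraries. Over all lost regions 9 of 445 lay beside a skipped number in a SAHA list, and 59 of the 4333 gained regions did so in an untreated list.

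**Figure D2:**
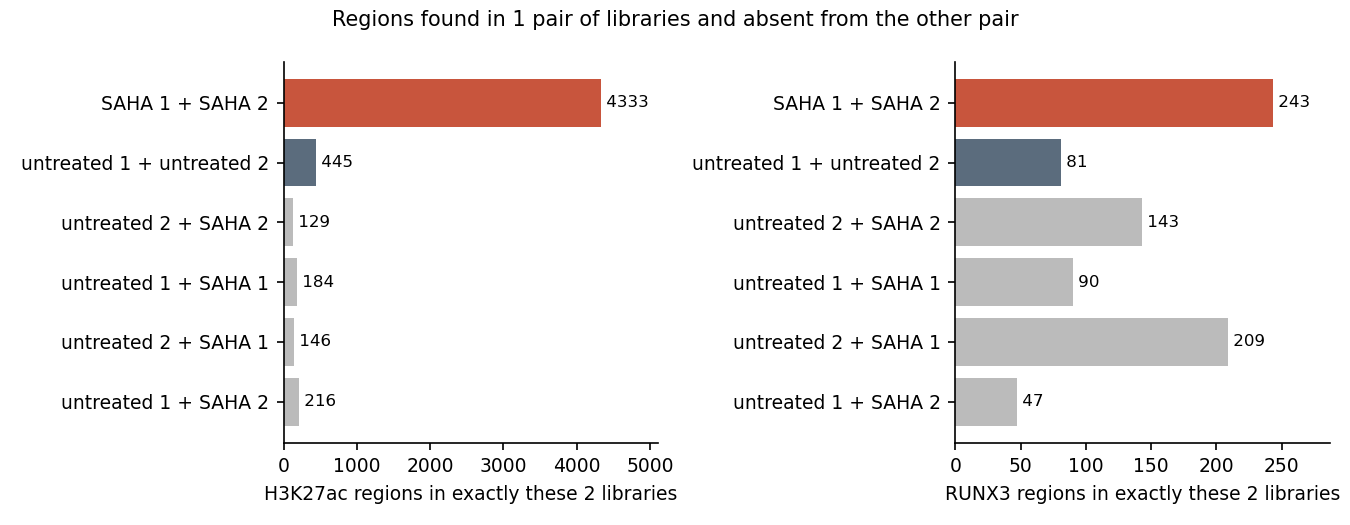
Number of merged regions found in exactly 1 pair of libraries, for H3K27ac (left) and RUNX3 (right), with the pair named on the vertical axis. Red bars are regions of both SAHA libraries, dark bars those of both untreated libraries, and grey bars those of mixed pairs. For H3K27ac the 4333 regions of the SAHA pair stand far above mixed pairs, whereas for RUNX3 the 243 regions of the SAHA pair lie near the 209 of a mixed pair.

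Regions acetylated in all 4 libraries also lengthened, a comparison added after the data were examined. Of the 22510, 13934 (61.9%) covered more bases in both SAHA libraries than in either untreated one and 1960 (8.71%) covered fewer, where chance ordering would give 16.7% each. The other 2 splits, which mix the treatments, gave 5.18% to 9.44%, so the 8.71% lay within their range and the 61.9% far above it. The median region covered 2003 bp in untreated and 2447 bp in SAHA-treated cells, a median log2 ratio of 0.21. A single SAHA peak spanned separate untreated peaks in 810 regions, and the converse held in 57. Of the net 18.3 Mb added, 71.9% lay in regions of all 4 libraries and 18.4% in gained regions. Regions were also grouped by their length in 1 untreated replicate and SAHA was compared with the other, so that the grouping length was not the one compared. Those under 1 kb had a median log2 ratio of 0.53 and 0.46 with replicates 1 and 2 as the grouping one, and those of 10 kb or longer 0.11 and 0.10. Expressed in bases, the median addition was 274 and 238 bp in the shortest class and 1231 and 1128 bp in the longest.

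Covered length was next compared along the genome in windows (bins) of 50 kb, since no gene annotation of hg19 was used here. Bins count all covered bases, those of gained and lost regions included. Of 15322 bins tested with limma on log2(covered bp + 500), 6081 were longer covered after SAHA and 324 shorter at a Benjamini-Hochberg false discovery rate of 0.05, with a median log2 change of 0.25. On that log2 scale the largest change was at chromosome 6 position 132200001 to 132250000, where acetylation was listed at 0 in both untreated libraries and covered 8.38 ± 0.365 kb (SD, n = 2) after SAHA (limma adjusted p = 0.0031). At chromosome 17 position 57700001 to 57750000 the covered length was 0.0925 ± 0.131 kb in untreated and 7.34 ± 0.344 kb in SAHA-treated cells (SD, n = 2), a log2 change of 3.74 ± 0.18 (SE, limma adjusted p = 0.0031). Neighbouring bins of chromosome 17, at 41750001 to 41800000 and 41800001 to 41850000, went from 0.253 ± 0.0940 to 7.50 ± 1.61 kb and from 0.167 ± 0.235 to 6.56 ± 0.465 kb (SD, n = 2). Chromosome 1 position 54050001 to 54100000 gained the most bases of the 5, from 0.701 ± 0.181 to 11.3 ± 1.11 kb (SD, n = 2), a log2 change of 3.30 ± 0.14 (SE). The 5 shortened bins of largest log2 change held under 3 kb of acetylation in untreated cells, while others of the 324 were more widely covered. Chromosome 3 position 109000001 to 109050000 covered 1.82 ± 0.241 kb and chromosome 1 position 199550001 to 199600000 covered 1.38 ± 0.0566 kb in untreated cells (SD, n = 2), and both were listed at 0 after SAHA (limma adjusted p = 0.0032 for each). Chromosome 8 position 97600001 to 97650000 went from 2.37 ± 0.189 to 0.230 ± 0.325 kb (SD, n = 2; limma adjusted p = 0.014, and 0.051 with a pseudocount of 100 bp). The bins at chromosome 10 position 80900001 and chromosome 3 position 13350001 went from 1.48 ± 0.897 and 1.42 ± 0.813 kb (SD, n = 2) to 0. Their limma adjusted p-values of 0.018 and 0.016 became 0.103 and 0.0978 without SAHA replicate 1 and 0.0972 and 0.0920 without SAHA replicate 2. No peak number was skipped in these 10 bins in any list.

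Scaling each library by its total covered length, which sets the overall rise aside, moved the median log2 change of all bins to −0.04 and left 2642 bins longer and 2054 shorter covered than that average, including all 10 named bins in their directions. With peaks of −log10 q 5 or more only 3 of the 10 were tested and called, those at chromosome 17 position 41750001 and 41800001 and at chromosome 1 position 54050001. The other 7, the chromosome 6 bin and all 5 shortened ones among them, fell short of the minimum covered length. With a SAHA library left out the calls were 1610 longer and 91 shorter without replicate 1 and 2298 longer and 110 shorter without replicate 2. Without untreated replicate 1 or 2 the median log2 change was 0.25 or 0.24. A tested bin needs the minimum covered length in 2 libraries. A bin below it in both libraries of a group drops out when a library of the other group is left out. None of the 5 named shortened bins could be tested without an untreated library. Of the longer ones, only that at chromosome 1 position 54050001 was tested without a SAHA library.

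**Figure D3:**
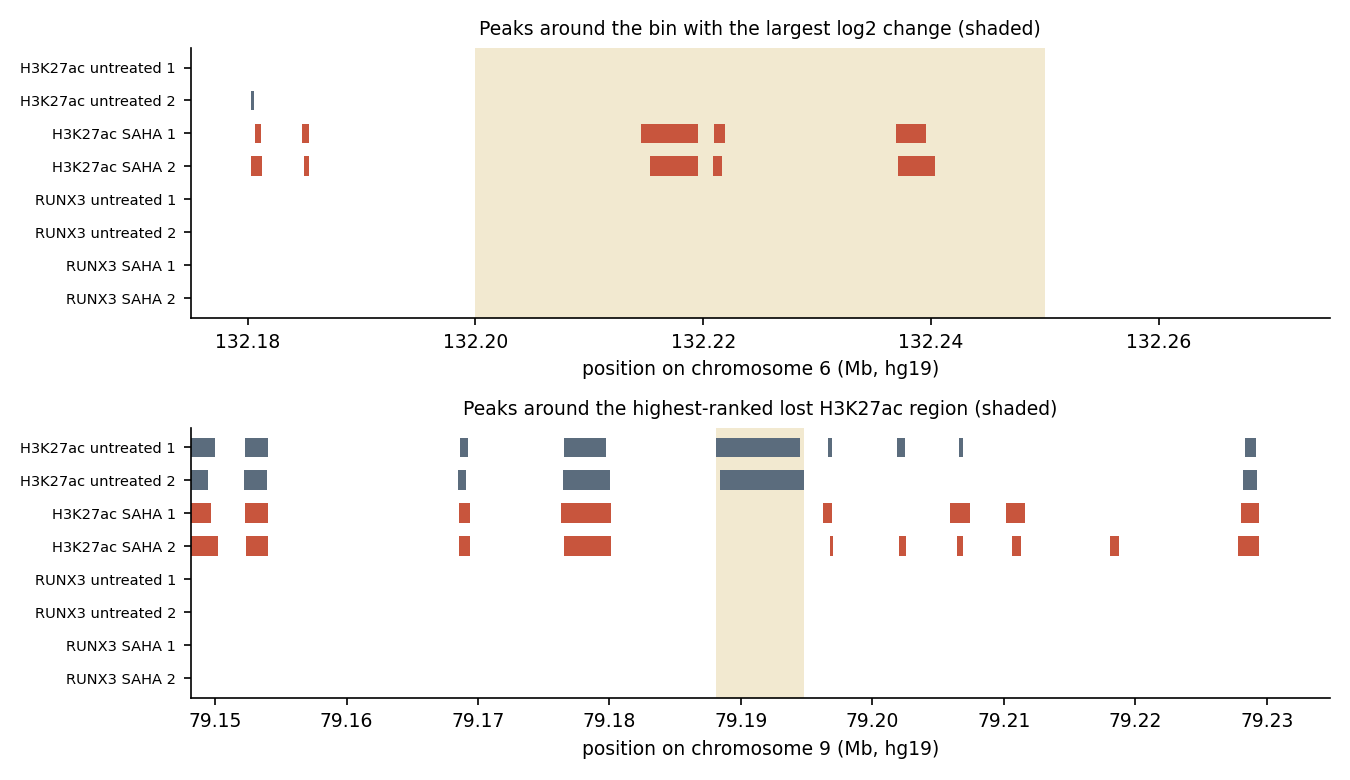
Peaks of the 8 libraries on hg19 (horizontal axis, Mb) around the 50-kb bin of chromosome 6 with the largest change in log2(covered bp + 500) (top) and around the highest-ranked lost H3K27ac region on chromosome 9 (bottom). Each row is 1 library, with untreated peaks in grey and SAHA peaks in red, and the named bin or region is shaded. In the lower map the neighbouring peaks are present in both treatments, and both SAHA lists skip 1 peak number within the gap.

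The second comparison asked whether SAHA changed RUNX3 binding. RUNX3 peak lists were short and varied as much between replicates as between treatments. They held 1565 and 2466 peaks in untreated cells and 2526 and 2161 peaks after SAHA. The means were 2016 ± 637 and 2344 ± 258 (SD, n = 2; two-sided exact permutation p = 0.667), so the difference did not exceed the replicate spread, and its change of 16.3% turned to −4.97% without untreated replicate 1 and 49.7% without untreated replicate 2. Covered length was 0.578 ± 0.175 Mb in untreated and 0.720 ± 0.0834 Mb in SAHA-treated cells (SD, n = 2; exact permutation p = 0.667), and its rise of 24.4% became 58.3% without untreated replicate 2 and 2.48% without untreated replicate 1. Peaks were slightly wider after SAHA, with a median of 252 ± 3.54 bp in untreated and 272 ± 4.95 bp in SAHA-treated cells (SD, n = 2; exact permutation p = 0.333, the smallest possible). Untreated replicates shared 0.339 of their joint peak length and SAHA replicates 0.402, and pairs of different treatment shared 0.356 to 0.365.

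Of 4052 merged RUNX3 regions, 854 (21.1%) were found in all 4 libraries and 1755 in 1 library only. After SAHA 243 were gained and 81 lost. Mixed pairs of libraries gave 47 to 209 such regions, so the gained count was above, and the lost count within, what pairs of unlike treatment gave. The highest-ranked gained region was chromosome 2 position 44980692 to 44980987, with a fold enrichment of 8.75 and 8.65 in the 2 SAHA lists. Next came chromosome 19 position 12888432 to 12888706, chromosome 6 position 108038053 to 108038288 and chromosome 11 position 9335993 to 9336373, each inside acetylation found in all 4 H3K27ac libraries. The region at chromosome 13 position 100089263 to 100089605 was gained for RUNX3 and lay in H3K27ac peaks of both SAHA libraries only. The highest-ranked lost region was chromosome 1 position 101756557 to 101756840, with a fold enrichment of 7.51 and 7.39 in the untreated lists. It was followed by chromosome 2 position 122288597 to 122288862 and by chromosome 9 positions 134273540 to 134273861 and 117481177 to 117481383, all acetylated in every library. The lost region at chromosome 6 position 45798173 to 45798425 held no H3K27ac peak in any library. With the same number of top peaks from each library, 112 regions were gained and 121 lost, though equal list lengths tie these 2 counts together. Mixed pairs then gave 83 to 97. With peaks of −log10 q 5 or more 146 were gained and 45 lost, and mixed pairs gave 37 to 141, close to the gained count. Leaving out untreated replicates 1 and 2 and SAHA replicates 1 and 2 gave 391, 529, 609 and 810 gained and 769, 225, 204 and 153 lost regions, in that order.

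The 854 RUNX3 regions of all 4 libraries were longer in both SAHA libraries in 26.8% of cases and shorter in 9.84%. The other splits gave 9.37% to 22.7%, close to these shares. The median log2 length ratio was 0.12, and 0.18 without untreated replicate 2. Of 1675 bins of 50 kb tested with limma on log2(covered bp + 200), 0 were longer and 0 shorter covered at a false discovery rate of 0.05. At an unadjusted p under 0.05, 166 were longer and 33 shorter, against 121 and 23 in one of the other splits and 79 and 47 in the other. On simulated RUNX3 bins limma recovered 80% of changes of 2 on the log2 scale and 20% of changes of 1, so changes of that smaller size would mostly have been missed. These simulated bins had the same spread at equal mean, so recovery in the real bins may be lower at either size.

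The third comparison asked where RUNX3 lay relative to H3K27ac. Most RUNX3 peaks lay in acetylated chromatin in both treatments. The share overlapping an H3K27ac peak of the same treatment was 88.0% ± 2.49 (SD, n = 2) in untreated and 95.1% ± 0.250 (SD, n = 2) in SAHA-treated cells, against 2.85% and 3.60% for the same peaks shifted along their chromosomes. With peaks of −log10 q 5 or more these shares were 76.7% ± 1.29 and 86.6% ± 0.584 (SD, n = 2). The difference of 7.20 percentage points was larger than the replicate spread (two-sided exact permutation p = 0.333, the smallest possible). It followed the H3K27ac lists and not the RUNX3 lists. Against the SAHA H3K27ac lists, untreated RUNX3 peaks overlapped in 94.3% ± 2.38 and SAHA RUNX3 peaks in 95.1% ± 0.250 of cases (SD, n = 2). Against the untreated H3K27ac lists the shares were 88.0% ± 2.49 and 87.5% ± 0.177 (SD, n = 2). Peaks outside every H3K27ac list made up 5.31% ± 2.36 of untreated and 4.38% ± 0.242 of SAHA RUNX3 peaks (SD, n = 2).

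**Figure D4:**
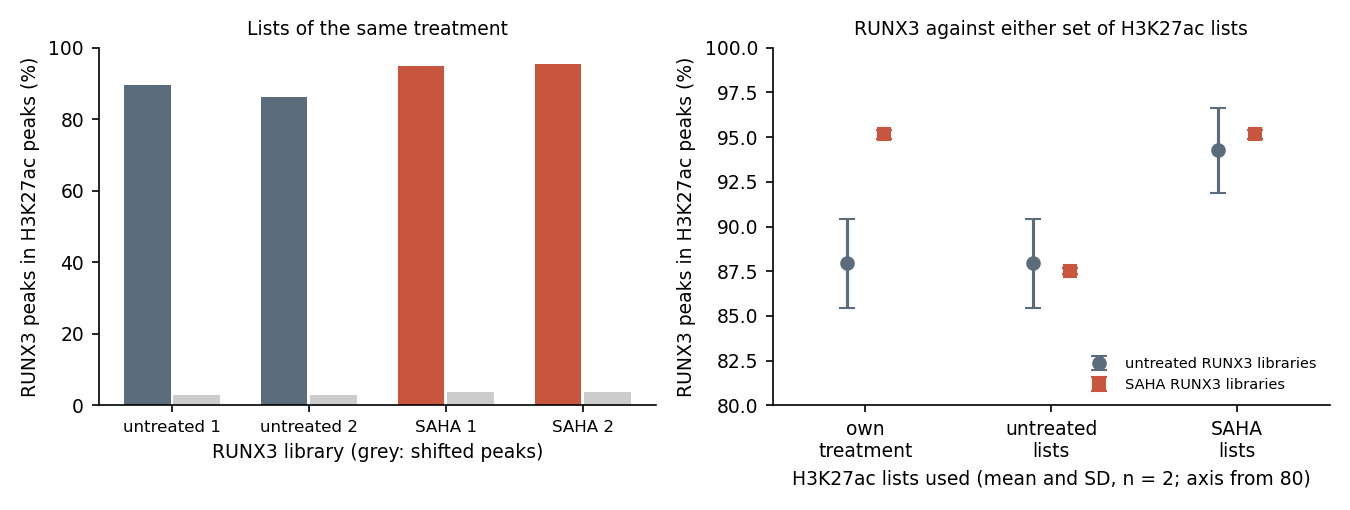
Left, percent of RUNX3 peaks overlapping H3K27ac peaks of the same treatment in each RUNX3 library, with the mean over 100 circular shifts in grey. Right, mean percent and SD (n = 2) of untreated and SAHA RUNX3 peaks against the H3K27ac lists of their own treatment, of untreated cells and of SAHA-treated cells, on an axis that starts at 80. With the same H3K27ac lists for both, the treatments differ by less than the SD of the untreated libraries.

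The last comparison asked whether RUNX3 and H3K27ac changed at the same places. Gained acetylation seldom held RUNX3. A RUNX3 region of any library overlapped 152 of 4333 gained H3K27ac regions (3.51%) and 3169 of the 22510 found in all 4 libraries (14.1%), an odds ratio of 0.222 (95% interval 0.187 to 0.262; two-sided Fisher's exact test, p = 2.85e-106, Benjamini-Hochberg adjusted over 4 tests 1.14e-105). Without H3K27ac SAHA replicate 1 or 2 it was 0.140 or 0.138. The difference followed region width. Per Mb, gained regions held 36.3 RUNX3 regions and those of all 4 libraries 40.4, and among regions of 500 to 2000 bp the shares were 3.36% and 3.08% (odds ratio 1.09, Fisher's exact p = 0.470). Lost acetylation held almost no RUNX3, with 1 of 445 regions (0.225%, odds ratio 0.0137, Fisher's exact p = 1.08e-27, adjusted 2.15e-27). With 1 library left out the odds ratio was 0.00472 to 0.0176. Within 500 to 2000 bp it was still 0.105 (Fisher's exact p = 0.0016). Lost regions were weak, however. By fold enrichment in the untreated lists, taking the lower replicate, their median lay at the 8.10th percentile. That of regions in all 4 libraries, which are wider and were ranked by the strongest of their peaks, lay at the 57.9th. Enrichment was not matched, so an effect of weak calls cannot be told apart from a lack of RUNX3 at lost acetylation. Of the gained RUNX3 regions, 87.7% lay at acetylation found in all 4 libraries, 4.94% (12 of 243) at gained acetylation and 6.17% outside every H3K27ac region. The share at gained acetylation was 3.86% for RUNX3 regions of all 4 libraries, and the difference did not pass the test (odds ratio 1.29, Fisher's exact p = 0.464, adjusted 0.619). Without RUNX3 SAHA replicate 2 the odds ratio was 1.63 with an unadjusted p of 0.0375. Of the 81 lost RUNX3 regions 0 lay at lost acetylation, against 1 of 854 (Fisher's exact p = 1). Regions of one genome are not independent replicates, so these tests compare the regions of these libraries.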

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

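Settings marked as added were chosen after seeing the data. With peaks of −log10 q 5 or more, gained and lost regions numbered 1343 and 308 for H3K27ac and 146 and 45 for RUNX3, the H3K27ac rise was 6.78% in peak number and 24.9% in covered length, 3054 H3K27ac bins were longer covered (11294 tested), and RUNX3 peaks within H3K27ac made up 76.7% in untreated and 86.6% in SAHA-treated cells, 9.90 points apart. With equal numbers of top peaks, gained and lost regions numbered 2202 and 906 for H3K27ac and 112 and 121 for RUNX3, and the H3K27ac covered length rose by 22.7% (added). Asking for an overlap of 50% of each peak, which also separates lengthened peaks, gave 3152 lost H3K27ac peaks and 6034 gained. These are peaks of replicate 1 and not merged regions. Scaling by total covered length gave 2642 bins longer and 2054 shorter covered. With the same H3K27ac lists for both treatments (added), the difference in RUNX3 peaks within H3K27ac was −0.456 points with untreated lists and 0.888 with SAHA lists. Among H3K27ac regions of 500 to 2000 bp (added), the odds ratio for RUNX3 at gained regions was 1.09. Leaving out each replicate gave ranges of 5244 to 7147 gained and 710 to 1350 lost H3K27ac regions, 391 to 810 gained and 153 to 769 lost RUNX3 regions, 1610 to 4668 bins longer and 91 to 178 shorter covered by H3K27ac, −4.97% to 49.7% in RUNX3 peak number, 2.48% to 58.3% in RUNX3 covered length, 0.0792 to 0.184 in the RUNX3 log2 length ratio (added) and odds ratios of 1.04 to 1.63 for gained RUNX3 at gained H3K27ac, 0.138 to 0.240 for RUNX3 at gained H3K27ac and 0.00472 to 0.0176 for RUNX3 at lost H3K27ac. Fewer libraries relax the rule for regions and leave limma fewer degrees of freedom, with the lone library assumed to vary like the pair; the cause of the other changes was not tested. With the replicate block, 5852 bins were longer and 328 shorter covered by H3K27ac, 5476 of the longer ones called without it too, and 0 RUNX3 bins were called. Same-numbered libraries deviated together with a correlation of −0.03 for H3K27ac and 0.02 for RUNX3, so the numbers do not pair them. RUNX3 gave 0 called bins under every setting run, with 22 to 362 longer at an unadjusted p under 0.05. H3K27ac covered more length, and gained exceeded lost H3K27ac regions (peaks in the 50% setting), under every setting run for them. Leaving out regions beside a skipped peak number (added) left 4274 gained and 436 lost H3K27ac and 230 gained and 80 lost RUNX3 regions. Other pseudocounts, no minimum length, bins of 25 or 100 kb (added) and joining peaks within 1 kb moved no count by over 1.5 times. All listed peaks lay on main chromosomes, so the setting for other contigs moved nothing. Loci of gene bodies plus 50 kb, promoter loci, promoter windows, gene lists and RUNX motifs were not run, since they need an hg19 annotation or genome. Unknown depth limits every absent peak.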

Other observations

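Every test in this part was chosen after the results were seen. Gained H3K27ac regions lay close to regions that already held acetylation in an untreated library. Of the 4333, 54.7% lay within 10 kb of a region with a peak in an untreated library, against a mean of 16.6% and a maximum of 19.0% over 100 circular shifts. Within 5 kb the share was 40.3% against 11.4%, and within 50 kb 84.5% against 38.6%. The edges of those nearby regions were merged over all 4 libraries, so some of the closeness may come from bases covered only after SAHA. Spacing was measured for gained regions only, so closeness is not shown to set them apart from other H3K27ac regions. Windows of 1 Mb were put into 5 equal groups by the covered length of 1 untreated replicate, and the SAHA mean was compared with the other replicate. With replicate 1 as the grouping one, covered length went from 37.8 to 47.7 Mb in the densest group, while far fewer bases were added in the sparsest group, which covered 0.799 Mb in the untreated library. The ratio was higher in the sparsest group, at 1.48 against 1.26 (1.48 and 1.23 with replicate 2 as the grouping one). The untreated replicates themselves differed by ratios of 0.980 to 1.02 across these groups. Among autosomes, gained regions per 100 found in all 4 libraries ran from 10.2 on chromosome 19 to 24.2 on chromosomes 3 and 21, and the ratio of covered lengths from 1.22 on chromosome 22 to 1.31 on chromosome 18.

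H3K27ac peaks were more numerous and longer in the SAHA libraries. With equal numbers of top peaks, 63.1% of the regions in all 4 libraries were longer in both SAHA libraries and 8.21% shorter. The weakest peaks of the longer lists were thus not needed for this difference. Kept peaks keep their called starts and ends, however, so the setting cannot test what lengthened them. Greater effective depth at peak calling stays open. At a fold enrichment of 4.9 to 5.1 the median −log10 p was 1.03 times as high in the SAHA libraries, and how covered length depends on this measure is not known beyond the replicate pairs, whose ratios of 0.982 and 0.974 went with 0.980 and 0.981 in covered length. A sequencing platform, run or read number that differs between treatments also cannot be told apart from SAHA, since the labels name a single platform for 0 of the 4 H3K27ac libraries, so an effect of SAHA on acetylation remains a hypothesis.

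The excess of gained over lost RUNX3 regions, 243 against 81 or 162 regions, may come from the short list of untreated replicate 1, which held 1565 peaks. In both other splits the pair with untreated replicate 1 also had the fewer regions, at 90 against 143 and 47 against 209. The larger of these excesses, 162 regions, was as large as that between the treatments. The short list was not traced to a step of the experiment, and a change of RUNX3 binding at single sites stays open.

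H3K27ac regions that held RUNX3 in all 4 RUNX3 libraries lengthened more after SAHA than other regions found in all 4 H3K27ac libraries. RUNX3 was scored within peaks of both untreated H3K27ac libraries, so that bases covered only in the SAHA libraries did not enter. The 719 such regions had a median log2 length ratio of 0.27 and the other 21791 one of 0.21, a difference of 0.058 without matching. If greater length or enrichment alone were behind this, regions closely matched on untreated length and fold enrichment should differ little. The median difference to 10 matched regions each was 0.114 (95% bootstrap interval 0.0941 to 0.133). Matching also on untreated peaks per region and acetylated bases within 25 kb left 0.0816 (0.0632 to 0.103). Matching on measured untreated values may leave part of the effect of length or enrichment, so they are not excluded. Regions under 1000 bp were not compared as a class of their own. Without matching, the difference varied with untreated length. It was 0.30 at 1000 to 2000 bp and 0.16 at 2000 to 5000 bp (permutation p = 0.0005 for each). At 5000 to 10000 bp it was 0.12 (permutation p = 0.0005), and at 10 kb or longer 0.02 (permutation p = 0.102). The intervals and permutations are over regions, so they do not measure the spread between replicates. No biological explanation was tested.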
